A study of Arabidopsis thaliana with 18 samples.

How the data were processed

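Leaves of Arabidopsis thaliana were sequenced in 18 libraries: WT, ml2 and ml5 at day 0 and day 7 of darkness, with 3 replicates each. The labels call the treatment dark and the lines knockdowns. Column names of the deposited table mark groups by CK (control check) and D, which were taken as day 0 and day 7, an inference from the labels. The extraction protocol mentions doxycycline, but no sample label gives it. Nothing in the sources states that replicates are separate plants, so p-values measure only the spread between these samples. How the knockdowns were made, the age of the plants, the time of day at harvest and the way RNA was enriched are not given in the sources used here.

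RNA was extracted with Trizol and made into libraries with a TruSeq kit. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12 and Bowtie2 2.0.6. The notes name the TAIR10 build, and also the rice build IRGSP-1.0 without saying what it was used for. The deposited table holds estimated counts per gene from the authors, judged by its values: 97.12% are whole numbers and 1937 genes have a fractional value. The counting tool and its settings are not given in the sources used here. Estimated counts were rounded to whole numbers before every fit.

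The table lists 27628 genes. Of these, 27420 matched nuclear genes of the TAIR10.1 annotation and 208 were organelle identifiers (88 chloroplast, 120 mitochondria). Totals ran from 14914598 to 20417396 counts per library. Genes were kept by filterByExpr with a minimum count of 10, which left 19493 tested and 8135 not tested. Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3) and fitted by the quasi-likelihood method as 6 group means over all libraries, without a replicate block. Comparisons were day 7 against day 0 in each genotype, each line against WT and ml5 against ml2 at each day, and for each line the difference of its dark response from that of WT, 11 in all. P-values are two-sided and adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. The common biological coefficient of variation was 5.63% and the prior degrees of freedom 17.3. SE of log2 fold changes come from this fit, and SD of levels from 3 libraries.

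Precision was tested on simulated data for ml2 against WT at day 7, over 18142 genes. Of 50 genes changed 1.25-fold 25 were called, of 50 changed 1.5-fold 47, and of 50 changed 2-fold and 4-fold all 50, with 4 false calls. With 3 libraries against 3, the smallest two-sided exact permutation p-value is 0.1, so calls rest on variance shared across genes by edgeR.

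Gene lists were fixed before the data were examined: 28 lists with 463 genes (photosynthesis, chlorophyll, senescence, starvation, autophagy, proteolysis, hormones, stress, clock, cell types and others), and 2 defined by identifier, the chloroplast-encoded and mitochondria-encoded genes. A list needed at least 3 tested members. Lists were tested with camera (limma 3.58.1) on voom values with a correlation of 0.01 between genes, and adjusted over all 330 tests of 30 lists in 11 comparisons. Some list members were not analysed here. Genes named in the text follow a rule, also fixed then: ML2, ML5 and their family, up to 3 members per list and comparison with the smallest adjusted p and non-overlapping replicates (no such condition for differences in dark response), and the 5 largest rises and falls with a mean of at least 5 CPM in a group, non-overlapping replicates and a symbol. In the dark comparisons of the lines, genes named in WT are given with their values there. Some genes that pass the rule were left out, among them those whose call ended under another setting.

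For a gene with 0 counts in every library of a group, a fold is a lower bound against a floor of 3 counts per library. Such bounds and floors cover counting error only. Alternatives fixed before the data were examined were RLE size factors, library sizes alone, no filter beyond 1 count, a stricter filter (at least 1 CPM in 3 libraries and a mean of 2), DESeq2 1.42.0, limma-voom, a fit of only the libraries compared, organelle genes left out, replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Alternatives for the overlap of the lines, which interaction genes are listed in the closing section, and the clock phases were chosen after seeing the data.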

Results

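RNA was measured in leaves of Arabidopsis thaliana, a small flowering plant used as a laboratory model, by RNA sequencing of the wild type (WT) and of 2 lines that the labels call knockdowns, ml2 and ml5. Leaves were taken at day 0 and at day 7 of a dark treatment, which gave 6 groups of 3 libraries. Of the 27628 listed genes, 19493 had enough counts to be tested. Day was the largest source of variation, with 88.0% of the variance on the first principal component and 2.86% on the second. Replicates of a group differed by 1.75 to 5.69 times counting noise (chi-square per degree of freedom), except for ml2 day 0 replicate 1, which stood 12.7 and 8.61 times apart from the other two libraries of its group. Below, n = 3 libraries per group, a value after a gene name is the log2 fold change ± SE from the fit over all 18 libraries, and levels are normalised counts (CPM), mean ± SD. Adjusted p-values are two-sided. For each gene named by the rule in a pairwise comparison, all 3 libraries of 1 group lay above all 3 of the other. Medians of lists are of log2 fold changes. Counts over a fixed list use the adjustment over all genes, and the count adjusted over the list alone is given where it differed.

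The first question was whether the targeted transcripts were lower in their lines. ML2 (AT2G42890, chromosome 2, 17849819 to 17854553) and ML5 (AT1G29400, chromosome 1, 10289998 to 10294630) encode Mei2-like proteins, which carry RNA-recognition motifs, and the positions are whole gene models of the TAIR10.1 annotation, whose nuclear chromosomes are those of TAIR10. ML2 stood at 61.2 ± 2.26 CPM in WT and 6.35 ± 1.02 in ml2 at day 0, or 10.4% of WT, and at 253 ± 5.0 and 27.9 ± 1.69 at day 7, or 11%. ML5 stood at 208 ± 5.85 CPM in WT and 1.21 ± 0.327 in ml5 at day 0, or 0.579%, and at 328 ± 14.5 and 0.690 ± 0.170 at day 7, or 0.211%. The other targeted gene was not lowered in either line: ML2 was higher in ml5 at day 0 (0.46 ± 0.058, adjusted p = 1.18e-07) and at day 7 (0.26 ± 0.050, adjusted p = 7.32e-05), and ML5 in ml2 differed by 0.11 ± 0.051 at day 0, which did not pass (adjusted p = 0.0847) but did with library sizes alone (0.22) and without ml2 day 0 replicate 2 (0.15), and by 0.18 ± 0.049 at day 7 (adjusted p = 0.00692), a call that ended without WT day 7 replicate 3, where the log2 fold change was 0.15. Of the other family members, ML1 was lower in ml2 at day 0 (-0.16 ± 0.057, adjusted p = 0.0214) and at day 7 (-0.27 ± 0.053, adjusted p = 0.000211). The day 0 call ended in the fit of only the libraries compared, without WT day 0 replicate 1 or 2 or ml2 day 0 replicate 2 or 3, and under library sizes alone, where the log2 fold change was -0.048. In ml5, ML1 did not pass at day 0 (0.012 ± 0.058, adjusted p = 0.901) or at day 7 (-0.048 ± 0.052, adjusted p = 0.491). ML4 did not pass in either line at either day, but was lower in ml2 at day 0 without WT day 0 replicate 2 (-0.24) or ml2 day 0 replicate 1 (-0.21). In WT, darkness raised ML2 (2.04 ± 0.056), ML1 (1.14 ± 0.055), ML4 (0.75 ± 0.081) and ML5 (0.65 ± 0.051), so all 4 tested genes rose (median 0.94, adjusted p = 0.0122, adjusted p = 0.111 with an estimated correlation). ML2 rose with darkness in the ml2 line as well (2.13 ± 0.081), from a lower level. TEL1 and TEL2 had 0 counts in every library.

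**Figure D1:**
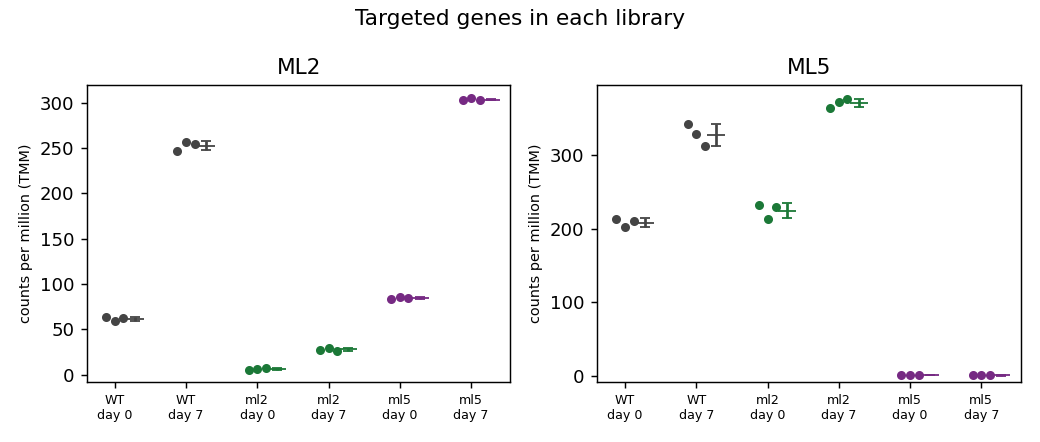
Level in CPM of ML2 and ML5 in each of the 18 libraries, with the mean and SD of each group of 3. ML2 stays at 27.9 CPM or lower on average in ml2, and ML5 at 1.21 CPM or lower in ml5.

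In WT, transcripts of the photosynthetic apparatus were lower after 7 days of darkness. Those of senescence and of the breakdown of amino acids and chlorophyll were higher. LHCB5, a light-harvesting protein of photosystem II, fell from 11385 ± 123 to 72.1 ± 3.31 CPM (-7.30 ± 0.052, adjusted p = 1.28e-39), and RBCS1A, a small subunit of Rubisco, from 15219 ± 182 to 96.8 ± 6.35 CPM (-7.30 ± 0.048). DIN6, an asparagine synthetase gene induced by darkness, rose from 11 ± 1.54 to 3720.3 ± 34.9 CPM (8.40 ± 0.089, adjusted p = 1.83e-35). HAI1, a senescence-associated protein phosphatase 2C, rose from 1.2 ± 0.224 to 400.1 ± 9.54 CPM (8.30 ± 0.094). Of the photosystem and light-harvesting genes encoded in the nucleus, all 42 tested genes fell (median -5.11, adjusted p = 2.09e-29). LHCB2.2 (-7.83 ± 0.048) and LHCB1.4 (-8.27 ± 0.058) were among them. In the Calvin cycle list, which covers carbon fixation, all 20 tested genes fell (median -5.51, adjusted p = 1.95e-16). FBA2 (-6.76 ± 0.047) and PRK (-8.11 ± 0.059) were examples. Among chlorophyll synthesis genes, all 23 tested genes fell (median -3.74, adjusted p = 8.78e-13). CRD1 (-5.26 ± 0.042), CHLP (-4.99 ± 0.044) and PORB (-5.91 ± 0.056) were among these. Reads of the LHCB1 and RBCS families fall on near-identical copies, so their division among members is uncertain. Of the chloroplast-encoded genes, all 88 tested genes fell (median -2.35, adjusted p = 3.25e-13, adjusted p = 0.262 with an estimated correlation), and their share of all counts went from 0.457% ± 0.0884 (SD) at day 0 to 0.176% ± 0.0395 at day 7.

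Genes that break down cell constituents went the other way in WT. In the leaf senescence list, 21 of the 24 tested genes rose, 2 fell and 1 did not pass (median 2.60, adjusted p = 4.56e-07). The transcription factor genes WRKY45 (4.92 ± 0.082) and WRKY75 (7.28 ± 0.15) were among them. SAG12, a cysteine protease gene used as a senescence marker, had 0 counts at day 0 and 88.2 ± 1.80 CPM at day 7, at least 426-fold higher against a floor of 3 counts per library. Of the dark and sugar starvation genes, 12 of the 14 tested genes rose and 2 fell (median 2.43, adjusted p = 0.000252), and DIN1 rose from 206 ± 13.7 to 3838 ± 58.0 CPM (4.22 ± 0.049). In amino acid catabolism, 22 of the 25 tested genes rose, 2 fell and 1 did not pass (median 2.65, adjusted p = 2.26e-10), and the largest by test were LKR/SDH (7.33 ± 0.061) of lysine breakdown, PRODH1 (7.05 ± 0.059) of proline breakdown and the glutamate dehydrogenase gene GDH2 (6.25 ± 0.056). In chlorophyll breakdown, 9 of the 11 tested genes rose and 2 fell (median 2.78, adjusted p = 0.000336). The chlorophyll b reductase gene NYC1 (4.09 ± 0.043), SGR1 (4.05 ± 0.057) and SGR2 (6.66 ± 0.10) were examples. In fatty acid beta-oxidation and gluconeogenesis, 12 of the 13 tested genes rose and 1 fell (median 1.5, adjusted p = 8.64e-06, adjusted p = 0.0903 with an estimated correlation). ACX2 (3.11 ± 0.048) and KAT2 (2.32 ± 0.038) were among these. Among vacuolar proteases and RNases, 7 of the 8 tested genes rose and 1 fell (median 1.05, adjusted p = 0.0102, adjusted p = 0.174 with an estimated correlation). RD21A (1.83 ± 0.036) and AALP (1.06 ± 0.039) were among them.

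Autophagy, the delivery of cell contents to the vacuole that the series title names, was a list fixed in advance. Of its core machinery, 36 of the 44 tested genes rose, 5 fell and 3 did not pass (median 0.80, adjusted p = 3.1e-06). The ubiquitin-like ATG8b (3.12 ± 0.072) and ATG8h (2.80 ± 0.083) and their activating enzyme ATG7 (3.48 ± 0.090) were examples. In the TOR and SnRK1 kinase list, which holds sensors of nutrient and energy status, 7 of the 11 tested genes rose and 4 did not pass (median 0.57, adjusted p = 0.0263, adjusted p = 0.0714 with an estimated correlation). S6K2 (3.49 ± 0.079) and KIN11 (1.0 ± 0.053) were among these. Of the 26S proteasome genes, 20 of the 32 tested genes rose, 4 fell and 8 did not pass (median 0.24, adjusted p = 0.0111, adjusted p = 0.131 with an estimated correlation). RPT3 (1.18 ± 0.048) and RPT6B (1.44 ± 0.060) were among them. Endoplasmic reticulum chaperone genes did not pass as a list, although 7 of the 8 tested genes rose and 1 fell (median 0.71, adjusted p = 0.0594). BZIP60 (1.46 ± 0.062) and BIP1 (1.07 ± 0.059) were examples. In the heat shock list, all 8 tested genes rose (median 5.57, adjusted p = 0.00599, adjusted p = 0.089 with an estimated correlation), among them HSP101, which went from 4.98 ± 0.764 to 103 ± 0.624 CPM; with members at or below the floor set to their bounds, that median was 3.09. Cytosolic ribosomal proteins did not pass as a list, where 2 of the 16 tested genes rose, 10 fell and 4 did not pass (median -0.21, adjusted p = 0.174), and with library sizes alone as the scaling their median was 0.18.

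Hormone and light lists were mixed in WT. In the abscisic acid list, 13 of the 17 tested genes rose and 4 fell (median 1.4, adjusted p = 0.042, adjusted p = 0.0832 with an estimated correlation, 0.0697 with library sizes alone). HAB1 (2.58 ± 0.064) was higher and COR15A (-5.17 ± 0.10) was lower. In the jasmonate list, 14 of the 21 tested genes rose and 7 fell (median 1.45, adjusted p = 0.0697), and members went apart, with the repressor gene JAZ1 (3.70 ± 0.059) up and AOC2 (-3.08 ± 0.053) and the defensin gene PDF1.2 (-5.73 ± 0.12) down. In the salicylic acid and immunity list, 9 of the 20 tested genes rose and 11 fell (median -0.24, adjusted p = 0.836, mean 0.13, the test pointing down). WRKY18 (2.85 ± 0.067) and FMO1 (5.45 ± 0.18) were higher and PAD4 (-2.01 ± 0.068) was lower. The list's median was 0.14 with library sizes alone. In the circadian clock list, 9 of the 19 tested genes rose, 8 fell and 2 did not pass, or 9 up and 9 down adjusted over the list alone (median 0.025, adjusted p = 0.99, mean 0.074, the test pointing down). PRR9 (1.29 ± 0.052) was higher and CHE (-2.97 ± 0.066) and LNK2 (-1.07 ± 0.043) were lower. Of light signalling genes, 3 of the 12 tested genes rose, 6 fell and 3 did not pass (median -0.60, adjusted p = 0.465). HY5 (3.47 ± 0.11) and HFR1 (2.76 ± 0.083) were higher and PIF5 (-1.71 ± 0.050) was lower. In flavonoid synthesis, 2 of the 9 tested genes rose, 5 fell and 2 did not pass (median -2.58, adjusted p = 0.459). The regulator PAP1 (4.18 ± 0.21) was higher and F3H (-4.82 ± 0.26) was lower.

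Xylem and epidermis marker lists fell in WT. Of the xylem markers, all 6 tested genes fell (median -3.99, adjusted p = 0.0438, adjusted p = 0.213 with an estimated correlation, 0.0512 to 0.0566 without WT day 7 replicate 1, 2 or 3), and with members at the floor set to their bounds the median was -3.61. Of the epidermis and trichome markers, 4 of the 5 tested genes fell and 1 did not pass (median -1.83, adjusted p = 0.0363, adjusted p = 0.273 with an estimated correlation). ATML1 (-2.21 ± 0.085) and PDF2 (-1.83 ± 0.073) were among these. In the cell division list, 13 of the 15 tested genes fell and 2 did not pass (median -1.88, adjusted p = 0.0495, adjusted p = 0.203 with an estimated correlation, 0.0524 to 0.0587 without WT day 0 replicate 2 or 3 or WT day 7 replicate 1, 2 or 3). CYCD3;1 (-2.79 ± 0.32) and MCM7 (-2.85 ± 0.34) were among them. Phloem markers went apart, where 2 of the 6 tested genes rose and 4 fell (median -0.46, adjusted p = 0.557). SWEET12 (2.02 ± 0.081) was higher and SUC2 (-2.45 ± 0.070) was lower. Guard cell markers did not pass, where 2 of the 5 tested genes rose, 2 fell and 1 did not pass (median -0.019, adjusted p = 0.984). MYB60 (-1.42 ± 0.15) was lower and KAT1 (0.69 ± 0.085) was higher, and that median was 0.36 with library sizes alone. Flower organ markers did not pass, where 1 of the 3 tested genes rose and 2 fell (median -1.60, adjusted p = 0.733). Of the mitochondria-encoded genes, 4 of the 68 tested genes rose, 20 fell and 44 did not pass, or 2 up and 17 down adjusted over the list alone (median -0.20, adjusted p = 0.563), a median of 0.18 with library sizes alone.

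The largest rises in WT by the naming rule were CCD8 of strigolactone synthesis, PCK2, a phosphoenolpyruvate carboxykinase gene, RLP22 and SAG12, with 0 counts at day 0 and at least 3375-fold, 644-fold, 476-fold and 426-fold higher levels at day 7, and DIN2, a beta-glucosidase gene that went from 0.0654 ± 0.0652 to 951 ± 2.76 CPM. The largest falls were NdhM, a subunit of the chloroplast NDH complex, the expansin gene EXPA8 and XTH31, with 0 counts at day 7 and at least 779.6-fold, 483-fold and 459.7-fold lower levels, and CAB3 (another name of LHCB1.2), which went from 8274 ± 225 to 0.718 ± 0.252 CPM. In all, 15964 of the 19493 tested genes passed, 8184 higher and 7780 lower, of which 3966 and 4870 differed by at least 2-fold. List calls numbered 19 of 30, 8 of them also with an estimated correlation. Scaled by library sizes alone, the split was 10545 higher and 5850 lower (64.3% higher, against 51.3% with TMM), and that scaling moved the median of all genes by 0.38. The split was 8078 higher and 7865 lower (50.7%) with RLE size factors and 8136 and 8024 (50.3%) with DESeq2.

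**Figure D2:**
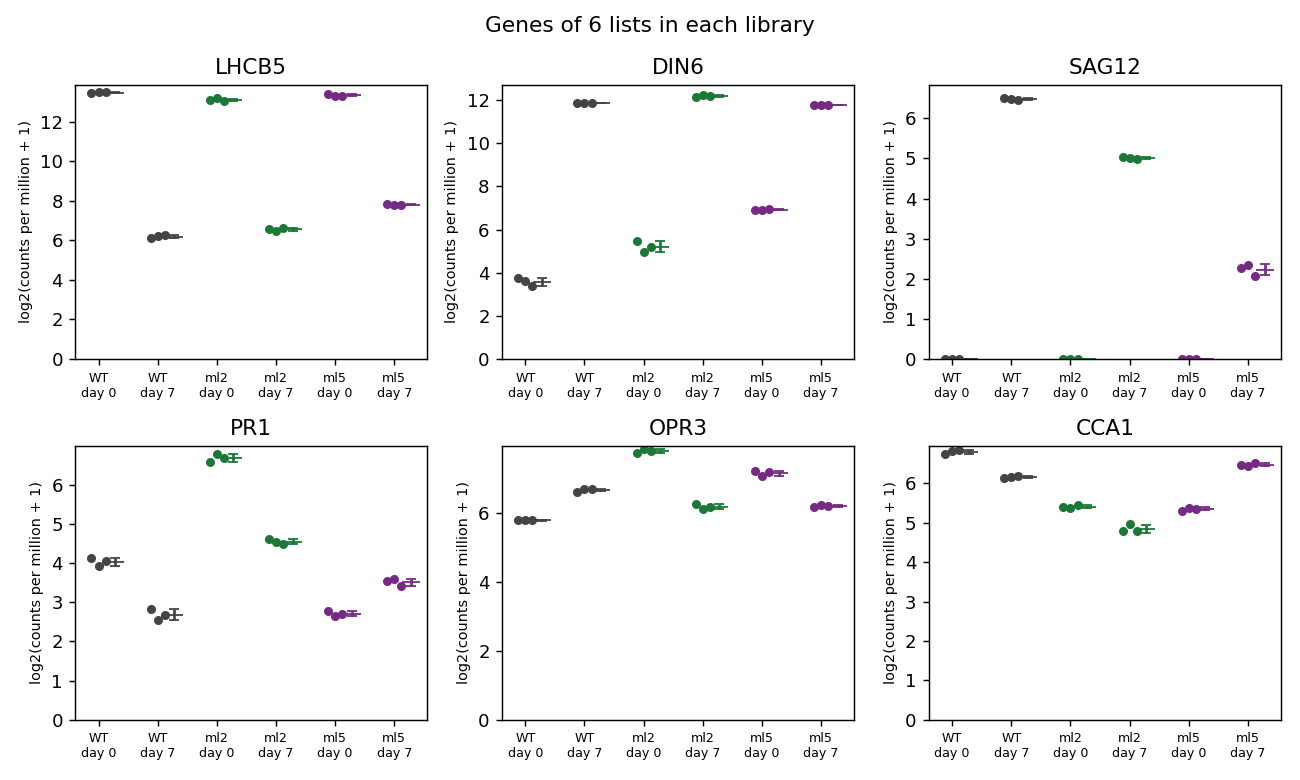
Level of 6 genes in each of the 18 libraries as log2(CPM + 1), with the mean and SD of each group of 3. LHCB5 falls and DIN6 rises with darkness in all 3 genotypes, and PR1 is highest in ml2 at day 0.

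In the ml2 line too, darkness lowered photosynthesis genes and raised those of senescence and amino acid catabolism. LHCB5 fell from 8796 ± 411 to 93.7 ± 4.70 CPM (-6.55 ± 0.050) and DIN6 rose from 36.2 ± 6.31 to 4704 ± 187 CPM (7.02 ± 0.080). In the photosystem list, all 42 tested genes fell (median -4.76, adjusted p = 9.25e-30). Among Calvin cycle genes, all 20 tested genes fell (median -4.72, adjusted p = 3.43e-16). In chlorophyll synthesis, all 23 tested genes fell (median -3.04, adjusted p = 2.14e-11). In leaf senescence, 19 of the 24 tested genes rose, 4 fell and 1 did not pass (median 1.45, adjusted p = 1.1e-05). HAI1 (5.07 ± 0.075) and WRKY45 (4.08 ± 0.070) were examples. Of the amino acid catabolism genes, 23 of the 25 tested genes rose and 2 fell (median 2.69, adjusted p = 6.27e-12). LKR/SDH (7.23 ± 0.060) and PRODH1 (7.55 ± 0.060) were among these. Of the autophagy machinery, 36 of the 44 tested genes rose, 7 fell and 1 did not pass (median 0.53, adjusted p = 3.41e-06). ATG8b (2.89 ± 0.067) and ATG7 (3.35 ± 0.088) were among them. In the jasmonate list, 7 of the 21 tested genes rose, 13 fell and 1 did not pass (median -0.30, adjusted p = 0.213). AOC2 (-4.56 ± 0.057) and PDF1.2 (-6.84 ± 0.10) were examples. In the salicylic acid and immunity list, 6 of the 20 tested genes rose, 13 fell and 1 did not pass (median -0.91, adjusted p = 0.0708). Of the heat shock genes, all 8 tested genes rose (median 3.42, adjusted p = 0.00624, adjusted p = 0.0914 with an estimated correlation), and the median was 2.48 with members at the floor set to their bounds. The largest rises included PCK2 and the polygalacturonase gene PGAZAT, with 0 counts at day 0 and at least 1792-fold and 431-fold higher levels at day 7, and the largest falls included NdhM and the cytokinin response regulator gene ARR7, at least 419-fold and 229.5-fold lower. In all, 15548 of the 19493 tested genes passed, 7714 higher and 7834 lower, of which 3459 and 4592 differed by at least 2-fold. List calls numbered 18 of 30, 9 of them also with an estimated correlation. With library sizes alone as the scaling, the split was 9406 higher and 6507 lower (59.1% higher, against 49.6% with TMM), and that scaling moved the median of all genes by 0.23. RLE size factors gave 7929 higher and 7674 lower (50.8%), and DESeq2 8023 and 7719 (51.0%).

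In the ml5 line, LHCB5 fell from 10391 ± 337 to 222 ± 4.77 CPM (-5.55 ± 0.047) and DIN6 rose from 119.8 ± 2.51 to 3508 ± 31.1 CPM (4.87 ± 0.071). In the photosystem list, all 42 tested genes fell (median -4.42, adjusted p = 1.59e-30). Among Calvin cycle genes, all 20 tested genes fell (median -4.02, adjusted p = 1.22e-16). In chlorophyll synthesis, all 23 tested genes fell (median -3.18, adjusted p = 2.23e-13). Of the leaf senescence genes, 19 of the 24 tested genes rose, 4 fell and 1 did not pass (median 1.69, adjusted p = 6.67e-05). HAI1 (5.29 ± 0.076) and WRKY45 (4.73 ± 0.081) were among these. In amino acid catabolism, 21 of the 25 tested genes rose, 2 fell and 2 did not pass (median 2.38, adjusted p = 7.04e-11). LKR/SDH (7.47 ± 0.063) and PRODH1 (6.96 ± 0.059) were among them. In chlorophyll breakdown, 10 of the 11 tested genes rose and 1 fell (median 2.2, adjusted p = 7.69e-06). Of the autophagy machinery, 34 of the 44 tested genes rose, 7 fell and 3 did not pass (median 0.63, adjusted p = 7.09e-06). ATG8b (3.22 ± 0.071) and ATG7 (2.65 ± 0.093) were examples. The jasmonate list did not pass, where 10 of the 21 tested genes rose, 10 fell and 1 did not pass (median 0.015, adjusted p = 0.998, mean -0.074, the test pointing up). Of the heat shock genes, all 8 tested genes rose (median 4.36, adjusted p = 0.0048, adjusted p = 0.0781 with an estimated correlation), with a median of 2.97 when members at the floor were set to their bounds. The largest rises included DIN2, the thioredoxin gene TH8 and the strigolactone synthesis gene CCD7, with 0 counts at day 0 and at least 3331-fold, 1392-fold and 435-fold higher levels at day 7, and the largest falls included NdhM and the auxin response gene IAA29, at least 430.5-fold and 163-fold lower. In all, 15557 of the 19493 tested genes passed, 7736 higher and 7821 lower, of which 3533 and 4595 differed by at least 2-fold. List calls numbered 15 of 30, 9 of them also with an estimated correlation. Scaled by library sizes alone, the split was 10544 higher and 5615 lower (65.3% higher, against 49.7% with TMM), and that scaling moved the median of all genes by 0.41. The split was 7927 higher and 7668 lower (50.8%) with RLE size factors and 7924 and 7776 (50.5%) with DESeq2. Across genes, which are not independent replicates, dark responses of WT and ml2 had a Pearson r of 0.948 and a slope of 0.846, and those of WT and ml5 0.935 and 0.841.

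Before darkness, ml2 differed from WT in defence and hormone genes. Unknown harvest times may add to every day 0 difference from WT. PR1, a marker of salicylic acid signalling, stood at 102 ± 7.45 against 15.4 ± 1.12 CPM in WT (2.71 ± 0.078, adjusted p = 2.4e-22), and PR2 (2.40 ± 0.054) and PR5 (2.43 ± 0.083) were higher too. In the salicylic acid and immunity list, 19 of the 20 tested genes were higher and 1 did not pass (median 1.41, adjusted p = 1.99e-15). In the jasmonate list, all 21 tested genes were higher (median 1.23, adjusted p = 4.93e-18). The synthesis gene OPR3 (2.02 ± 0.053), TAT3 (2.70 ± 0.078) and PDF1.2 (2.05 ± 0.071) were among these. Leaf senescence genes were raised, where 19 of the 24 tested genes were higher, 1 lower and 4 did not pass, or 19 up and 2 down adjusted over the list alone (median 0.99, adjusted p = 1.27e-09). SAG21 (2.03 ± 0.069), SAG13 (2.33 ± 0.10) and WRKY53 (1.65 ± 0.067) were among them. Of the dark and sugar starvation genes, 11 of the 14 tested genes were higher, 1 lower and 2 did not pass (median 0.59, adjusted p = 4.93e-06). DIN11 (2.70 ± 0.090), DIN6 (1.72 ± 0.090) and DIN1 (1.46 ± 0.045) were examples. In amino acid catabolism, 14 of the 25 tested genes were higher, 1 lower and 10 did not pass (median 0.25, adjusted p = 9.53e-06). BCAT2 (2.17 ± 0.073) and GDH1 (1.0 ± 0.053) were among these. In the abscisic acid list, 10 of the 17 tested genes were higher, 1 lower and 6 did not pass, or 11 up and 1 down adjusted over the list alone (median 0.53, adjusted p = 0.00143). RD29A (1.43 ± 0.086) and HAI1 (2.01 ± 0.16) were among them. Of the endoplasmic reticulum chaperone genes, all 8 tested genes were higher (median 0.45, adjusted p = 9.04e-05). BIP3 (2.12 ± 0.22) and BZIP60 (0.94 ± 0.063) were examples. In the autophagy list, 17 of the 44 tested genes were higher, 1 lower and 26 did not pass (median 0.19, adjusted p = 0.00362). The cargo receptor gene NBR1 (0.55 ± 0.045) and ATG8d (0.86 ± 0.11) were among these.

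Photosynthesis genes were lower in ml2 at day 0. In the Calvin cycle list, 1 of the 20 tested genes was higher and 19 lower (median -0.69, adjusted p = 1.37e-22). RBCS1B (-1.36 ± 0.051), RBCS2B (-1.08 ± 0.045) and the Rubisco activase gene RCA (-0.71 ± 0.031) were among them. Of the photosystem and light-harvesting genes, 38 of the 42 tested genes were lower and 4 did not pass, or 0 up and 39 down adjusted over the list alone (median -0.32, adjusted p = 1.59e-26). LHCB2.3 (-1.01 ± 0.051) and LHCB6 (-0.65 ± 0.040) were examples. Of the chlorophyll synthesis genes, 22 of the 23 tested genes were lower and 1 did not pass (median -0.55, adjusted p = 2.67e-16). CAO (-0.67 ± 0.042), HEMA1 (-0.64 ± 0.041) and CRD1 (-0.61 ± 0.034) were among these. Of the chloroplast-encoded genes, 79 of the 88 tested genes were lower and 9 did not pass, or 0 up and 82 down adjusted over the list alone (median -0.76, adjusted p = 5.08e-14, adjusted p = 0.247 with an estimated correlation), and their share of counts was 0.309% ± 0.049 in ml2 against 0.457% ± 0.0884 in WT. Of the mitochondria-encoded genes, 24 of the 68 tested genes were lower and 44 did not pass, or 0 up and 15 down adjusted over the list alone (median -0.54, adjusted p = 0.00876, adjusted p = 0.382 with an estimated correlation, 0.0503 without ml2 day 0 replicate 1). In the clock list, 7 of the 19 tested genes were higher, 10 lower and 2 did not pass (median -0.17, adjusted p = 0.113). CCA1 (-1.41 ± 0.057), LNK2 (-1.0 ± 0.043) and LNK1 (-0.83 ± 0.047) were lower. The largest rises by the naming rule were UGT76B1 (4.41 ± 0.32), EXPA16 (4.04 ± 0.21), MLO12 (3.87 ± 0.16), ERF53 (3.67 ± 0.16) and the cell wall invertase gene ATBFRUCT1 (3.50 ± 0.10). The largest falls by that rule were MRD1 (-5.02 ± 0.28), ML2 itself (-3.27 ± 0.077), AGP17 (-2.18 ± 0.088), BZIP34 (-2.12 ± 0.18) and SOFL1 (-2.02 ± 0.17). In all, 8677 of the 19493 tested genes passed, 4274 higher and 4403 lower, of which 1009 and 452 differed by at least 2-fold. List calls numbered 15 of 30, 11 of them also with an estimated correlation. With library sizes alone as the scaling, the split was 6075 higher and 3021 lower (66.8% higher, against 49.3% with TMM), and that scaling moved the median of all genes by 0.11. RLE size factors gave 3786 higher and 4994 lower (43.1%), and DESeq2 3617 and 4658 (43.7%). Without ml2 day 0 replicate 1, 9357 genes passed, 8067 of them also called with it.

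In ml5 at day 0, starvation and amino acid catabolism genes were higher and the Calvin cycle was lower. DIN6 stood at 119.8 ± 2.51 against 11 ± 1.54 CPM in WT (3.44 ± 0.085, adjusted p = 6.22e-24). In the dark and sugar starvation list, 10 of the 14 tested genes were higher, 1 lower and 3 did not pass, or 10 up and 3 down adjusted over the list alone (median 0.81, adjusted p = 7.84e-08). DIN1 (1.62 ± 0.045) and DIN10 (1.05 ± 0.045) were among them. In amino acid catabolism, 17 of the 25 tested genes were higher, 3 lower and 5 did not pass (median 0.25, adjusted p = 3.48e-05). GDH1 (1.14 ± 0.053), MCCA (0.91 ± 0.049) and BCAT2 (1.16 ± 0.080) were examples. Of the Calvin cycle genes, 1 of the 20 tested genes was higher, 17 lower and 2 did not pass (median -0.41, adjusted p = 5.49e-14). RBCS1B (-1.06 ± 0.051) and RCA (-0.54 ± 0.031) were among these. Of the photosystem genes, 5 of the 42 tested genes were higher, 21 lower and 16 did not pass, or 5 up and 22 down adjusted over the list alone (median -0.10, adjusted p = 7.97e-05, adjusted p = 0.4 with an estimated correlation). LHCB2.3 (-0.48 ± 0.051) and PSBS (-0.42 ± 0.050) were among them. In the jasmonate list, 13 of the 21 tested genes were higher, 1 lower and 7 did not pass, or 16 up and 1 down adjusted over the list alone (median 0.42, adjusted p = 4.46e-06). OPR3 (1.38 ± 0.054), AOC1 (0.76 ± 0.047) and AOC3 (2.05 ± 0.13) were examples. In the abscisic acid list, 10 of the 17 tested genes were higher, 1 lower and 6 did not pass, or 12 up and 1 down adjusted over the list alone (median 0.34, adjusted p = 0.000419). RD29A (2.05 ± 0.086), HAI1 (2.21 ± 0.16) and CYP707A3 (1.98 ± 0.12) were among these. The salicylic acid and immunity list did not pass, where 7 of the 20 tested genes were higher, 6 lower and 7 did not pass (median -0.024, adjusted p = 0.569). PR1 (-1.49 ± 0.11) and WRKY70 (-0.94 ± 0.059) were lower and FRK1 (2.83 ± 0.26) was higher. Of the leaf senescence genes, 9 of the 24 tested genes were higher, 4 lower and 11 did not pass, or 11 up and 4 down adjusted over the list alone (median 0.19, adjusted p = 0.0385, adjusted p = 0.222 with an estimated correlation, 0.0541 without WT day 0 replicate 1). WRKY6 (2.13 ± 0.092) and SAG21 (1.52 ± 0.070) were among them. Phloem markers were raised, where 4 of the 6 tested genes were higher and 2 did not pass (median 0.24, adjusted p = 0.00403). The sugar exporter gene SWEET12 (1.85 ± 0.084) was among them. In the autophagy list, which did not pass, 13 of the 44 tested genes were higher, 4 lower and 27 did not pass (median 0.090, adjusted p = 0.193). ATI1 (0.56 ± 0.054) and ATG18b (0.74 ± 0.13) were among these.

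Chloroplast-encoded genes were higher in ml5 at day 0, where 67 of the 88 tested genes were higher and 21 did not pass, or 73 up and 0 down adjusted over the list alone (median 0.59, adjusted p = 3.85e-14, adjusted p = 0.245 with an estimated correlation), at 0.743% ± 0.0643 of counts against 0.457% ± 0.0884 in WT. The mitochondria-encoded list did not pass, where 9 of the 68 tested genes were higher, 1 lower and 58 did not pass, or 4 up and 0 down adjusted over the list alone (median 0.15, adjusted p = 0.275). In the clock list, 7 of the 19 tested genes were higher, 9 lower and 3 did not pass, or 8 up and 9 down adjusted over the list alone (median -0.13, adjusted p = 0.161). CCA1 (-1.47 ± 0.059), LNK1 (-1.02 ± 0.048) and LNK2 (-0.81 ± 0.043) were lower. The largest rises by the naming rule were PHI-1 (5.77 ± 0.12), EXPA16 (4.67 ± 0.20), ERF53 (4.64 ± 0.16), EXO (4.57 ± 0.13) and MLO12 (4.31 ± 0.15), and the largest falls after ML5 itself were MRD1 (-4.76 ± 0.29), the abscisic acid hydroxylase gene CYP707A2 (-2.95 ± 0.29), SQP1 (-2.32 ± 0.10) and TZP (-2.31 ± 0.10). In all, 7467 of the 19493 tested genes passed, 3804 higher and 3663 lower, of which 613 and 491 differed by at least 2-fold. List calls numbered 13 of 30, 6 of them also with an estimated correlation. Scaled by library sizes alone, the split was 3994 higher and 3435 lower (53.8% higher, against 50.9% with TMM). The split was 3374 higher and 4119 lower (45.0%) with RLE size factors and 3193 and 3922 (44.9%) with DESeq2.

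At day 0, 2425 genes were higher in both lines and 2570 lower in both, against 834.1 and 827.4 for independent lists of these sizes (n1 × n2 / N), and 408 went opposite ways. MRD1, EXPA16, ERF53, MLO12 and CCA1 were among the genes called the same way in both. Both comparisons use the same 3 WT libraries. In 10 simulations of unchanged groups and controls, no gene was called the same way in both. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.57, against 0.52 simulated, and a covariance of 0.275 against 0.0458, a difference of 0.229. A state of the WT leaves was not simulated and the 3 controls cannot be split, so part of the excess may come from them.

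At day 7, ml2 had higher starvation and immunity transcripts than WT, while abscisic acid and jasmonate genes were lower. In the dark and sugar starvation list, 13 of the 14 tested genes were higher and 1 lower (median 0.59, adjusted p = 1.28e-16), with TPS8 (1.12 ± 0.045), DIN9 (0.93 ± 0.062) and DIN10, which stood at 4593 ± 226 against 3060.5 ± 27.8 CPM in WT. Of the amino acid catabolism genes, 19 of the 25 tested genes were higher and 6 did not pass, or 20 up and 0 down adjusted over the list alone (median 0.27, adjusted p = 1.22e-15). GDH1 (0.74 ± 0.055), BCE2 (0.58 ± 0.047) and PRODH1 (0.56 ± 0.043) were among them. In the salicylic acid and immunity list, 14 of the 20 tested genes were higher, 1 lower and 5 did not pass (median 0.39, adjusted p = 1.09e-07). PR1 (2.04 ± 0.095), the camalexin synthesis gene PAD3 (1.83 ± 0.083) and PR2 (1.17 ± 0.061) were examples. In the abscisic acid list, 1 of the 17 tested genes was higher, 11 lower and 5 did not pass, or 1 up and 14 down adjusted over the list alone (median -0.47, adjusted p = 1.43e-08), with HAI1 at 170.4 ± 3.95 against 400.1 ± 9.54 CPM in WT (-1.23 ± 0.051, adjusted p = 4.29e-18) and HAI2 (-1.69 ± 0.089). Of the jasmonate genes, 6 of the 21 tested genes were higher, 13 lower and 2 did not pass (median -0.30, adjusted p = 0.000173). MYC2 (-0.92 ± 0.051) and AOC2 (-0.93 ± 0.058) were lower and TAT3 (1.97 ± 0.087) was higher. Leaf senescence members went apart, where 13 of the 24 tested genes were higher, 6 lower and 5 did not pass, or 13 up and 7 down adjusted over the list alone (median 0.21, adjusted p = 0.156). SAG12 (-1.5 ± 0.070) was lower and NAP (0.63 ± 0.052) was higher. Of the chlorophyll breakdown genes, 6 of the 11 tested genes were lower and 5 did not pass, or 1 up and 7 down adjusted over the list alone (median -0.14, adjusted p = 0.000214). TIC55 (-0.59 ± 0.048) and SGR1 (-0.31 ± 0.046) were among these. In the clock list, 1 of the 19 tested genes was higher, 9 lower and 9 did not pass, or 2 up and 9 down adjusted over the list alone (median -0.18, adjusted p = 3.41e-06). PRR9 (-1.48 ± 0.051), LNK1 (-1.27 ± 0.047) and CCA1 (-1.34 ± 0.059) were among them.

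Light signalling genes also differed in ml2 at day 7, where 6 of the 12 tested genes were higher, 3 lower and 3 did not pass (median 0.13, adjusted p = 0.00641). ATHB2 (2.1 ± 0.071) and HFR1 (1.72 ± 0.059) were higher and HY5 (-1.12 ± 0.081) was lower. In the heat shock list, 3 of the 8 tested genes were lower and 5 did not pass (median -0.34, adjusted p = 0.00074). HSP101 (-1.42 ± 0.073) and HSFA2 (-1.32 ± 0.10) were examples. The photosystem list did not pass, where 12 of the 42 tested genes were higher, 8 lower and 22 did not pass, or 14 up and 9 down adjusted over the list alone (median 0.071, adjusted p = 0.182). LHCB1.4 (0.91 ± 0.051) was higher and LHCB2.1 (-0.47 ± 0.040) was lower. Of the autophagy machinery, 12 of the 44 tested genes were higher and 32 did not pass, or 14 up and 1 down adjusted over the list alone (median 0.080, adjusted p = 0.0382, adjusted p = 0.0506 with an estimated correlation, 0.0847 with library sizes alone, 0.0512 without WT day 7 replicate 3, 0.0553 without ml2 day 7 replicate 3). ATG8e (0.56 ± 0.069) and ATI1 (0.30 ± 0.050) were among these. The largest rises were FAR5 (3.25 ± 0.27), MAF5 (2.71 ± 0.11), the camalexin synthesis gene CYP71A13 (2.64 ± 0.11), MSRB7 (2.61 ± 0.12) and PRXCA (2.47 ± 0.17), and the largest falls after ML2 were cPT4 (-3.02 ± 0.10), MRD1 (-2.88 ± 0.22), TPS03 (-2.72 ± 0.16) and PUB19 (-2.65 ± 0.091). In all, 5036 of the 19493 tested genes passed, 2613 higher and 2423 lower, of which 319 and 244 differed by at least 2-fold. List calls numbered 14 of 30, 9 of them also with an estimated correlation. With library sizes alone as the scaling, the split was 2178 higher and 3109 lower (41.2% higher, against 51.9% with TMM). RLE size factors gave 2653 higher and 2361 lower (52.9%), and DESeq2 2479 and 2164 (53.4%).

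At day 7, ml5 had more photosynthesis transcripts than WT and fewer of senescence. LHCB5 stood at 222 ± 4.77 against 72.1 ± 3.31 CPM in WT (1.62 ± 0.042, adjusted p = 4.1e-23) and SAG12 at 3.71 ± 0.468 against 88.2 ± 1.80 CPM (-4.57 ± 0.091, adjusted p = 4.31e-22). In the photosystem list, 39 of the 42 tested genes were higher, 1 lower and 2 did not pass, or 40 up and 1 down adjusted over the list alone (median 0.46, adjusted p = 2.11e-19, adjusted p = 0.065 with an estimated correlation). LHCB1.3 (1.5 ± 0.039) and LHCA2 (1.09 ± 0.034) were among them. Of the Calvin cycle genes, 17 of the 20 tested genes were higher and 3 did not pass, or 18 up and 0 down adjusted over the list alone (median 0.71, adjusted p = 4.78e-13). PRK (1.53 ± 0.061), RBCS1A (1.39 ± 0.038) and FBA2 (1.27 ± 0.041) were examples. Of the chlorophyll synthesis genes, 15 of the 23 tested genes were higher and 8 did not pass, or 15 up and 1 down adjusted over the list alone (median 0.29, adjusted p = 1.51e-06). CHLP (0.99 ± 0.040) was among these. In the ribosomal protein list, 14 of the 16 tested genes were higher and 2 lower (median 0.44, adjusted p = 1.63e-07). RPS6B (0.94 ± 0.050) was among them. In leaf senescence, 1 of the 24 tested genes was higher, 16 lower and 7 did not pass (median -0.44, adjusted p = 1.62e-07). SWEET15 (-2.88 ± 0.13) and VNI2 (-0.88 ± 0.046) were examples. Of the chlorophyll breakdown genes, 1 of the 11 tested genes was higher, 8 lower and 2 did not pass (median -0.23, adjusted p = 0.000476). SGR1 (-0.80 ± 0.046) and SGR2 (-0.76 ± 0.057) were among these. Of the jasmonate genes, 2 of the 21 tested genes were higher, 16 lower and 3 did not pass (median -0.46, adjusted p = 1.66e-07). JAZ1 (-1.28 ± 0.049) and AOC2 (-1.13 ± 0.058) were among them. Of the 26S proteasome genes, 18 of the 32 tested genes were lower and 14 did not pass, or 0 up and 20 down adjusted over the list alone (median -0.18, adjusted p = 0.000205). RPT6B (-0.47 ± 0.054) was among them. Of the endoplasmic reticulum chaperones, 7 of the 8 tested genes were lower and 1 did not pass, or 0 up and 8 down adjusted over the list alone (median -0.43, adjusted p = 0.00114). BIP1 (-0.51 ± 0.057) was among them.

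Light signalling genes differed in ml5 at day 7 as well, where 7 of the 12 tested genes were higher, 2 lower and 3 did not pass (median 0.44, adjusted p = 0.00261). ATHB2 (2.49 ± 0.070) and HFR1 (1.75 ± 0.059) were higher. The dark and sugar starvation list did not pass, where 6 of the 14 tested genes were higher, 3 lower and 5 did not pass (median 0.087, adjusted p = 0.24). TPS8 (0.97 ± 0.045) was higher and DIN11 (-1.64 ± 0.078) was lower. The autophagy list did not pass either, where 7 of the 44 tested genes were higher, 12 lower and 25 did not pass (median -0.091, adjusted p = 0.493). ATG7 (-0.83 ± 0.070) and ATG1a (-0.48 ± 0.053) were lower and ATI1 (0.47 ± 0.050) was higher. In the clock list, 10 of the 19 tested genes were higher, 5 lower and 4 did not pass (median 0.22, adjusted p = 0.0823). RVE4 (0.66 ± 0.054) and LUX (0.62 ± 0.062) were higher and PRR9 (-0.55 ± 0.049) was lower. The largest rises were PR5 (2.76 ± 0.16), ACD6 (2.60 ± 0.074), ATHB2, the myrosinase gene TGG2 (2.31 ± 0.044) and OXS3 (2.25 ± 0.081). The largest falls after ML5 were SAG12, the polygalacturonase gene PGAZAT (-3.39 ± 0.10), MRD1 (-3.26 ± 0.22) and SWEET15. In all, 8444 of the 19493 tested genes passed, 3762 higher and 4682 lower, of which 498 and 481 differed by at least 2-fold. List calls numbered 12 of 30, 9 of them also with an estimated correlation. Scaled by library sizes alone, the split was 4307 higher and 4072 lower (51.4% higher, against 44.6% with TMM). The split was 3817 higher and 4616 lower (45.3%) with RLE size factors and 3601 and 4312 (45.5%) with DESeq2.

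At day 7, 1271 genes were higher in both lines and 1375 lower in both, against 504.3 and 582 for independent lists, and 777 went opposite ways. ATHB2, HFR1, TPS8, PR2 and ATI1 were higher in both lines, and MRD1, SAG12, AOC2, PRR9 and HAI1 were lower in both. Simulated unchanged groups gave a mean of 0.1 genes higher and 0 lower. Across genes, the Pearson r was 0.40 against 0.50 simulated, and the covariance 0.114 against 0.0319, a difference of 0.0817. As at day 0, the lines share 3 WT libraries that cannot be split, so part of the excess may come from the shared controls.

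**Figure D3:**
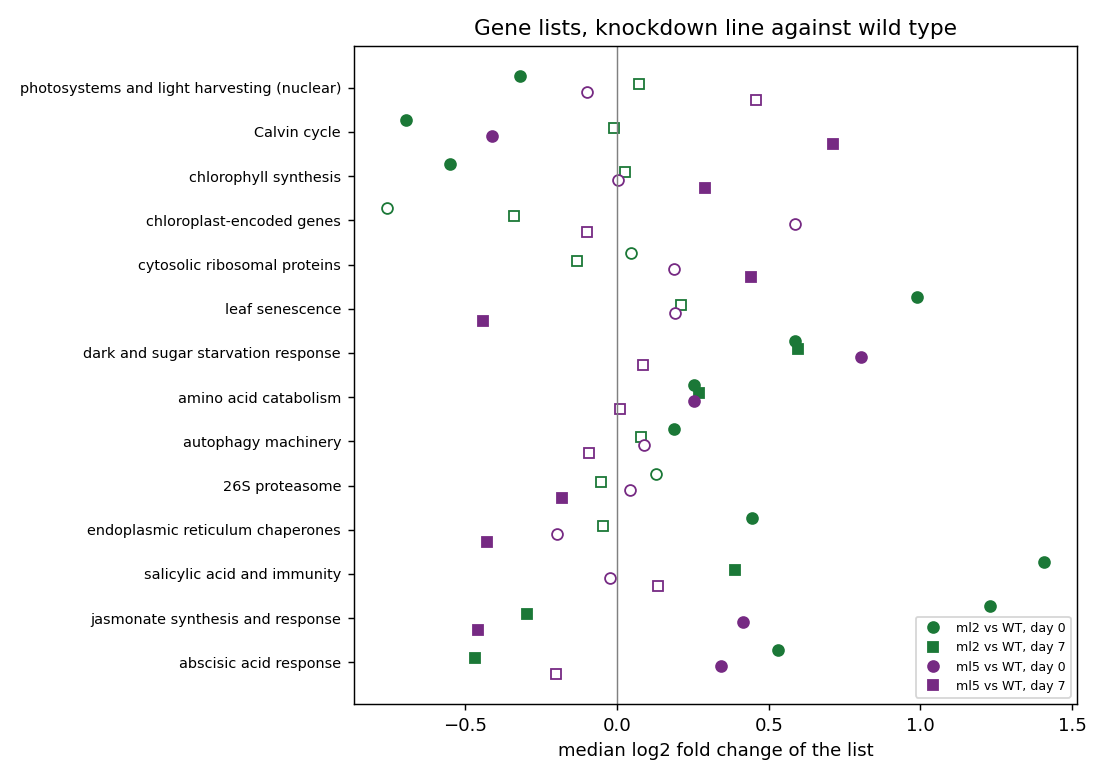
Median log2 fold change of 14 gene lists in ml2 and ml5 against WT, with circles for day 0 and squares for day 7, and filled symbols for list calls that held with an estimated correlation. Jasmonate genes lie above WT at day 0 and below WT at day 7 in both lines (1.23 and -0.30 in ml2).

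**Figure D4:**
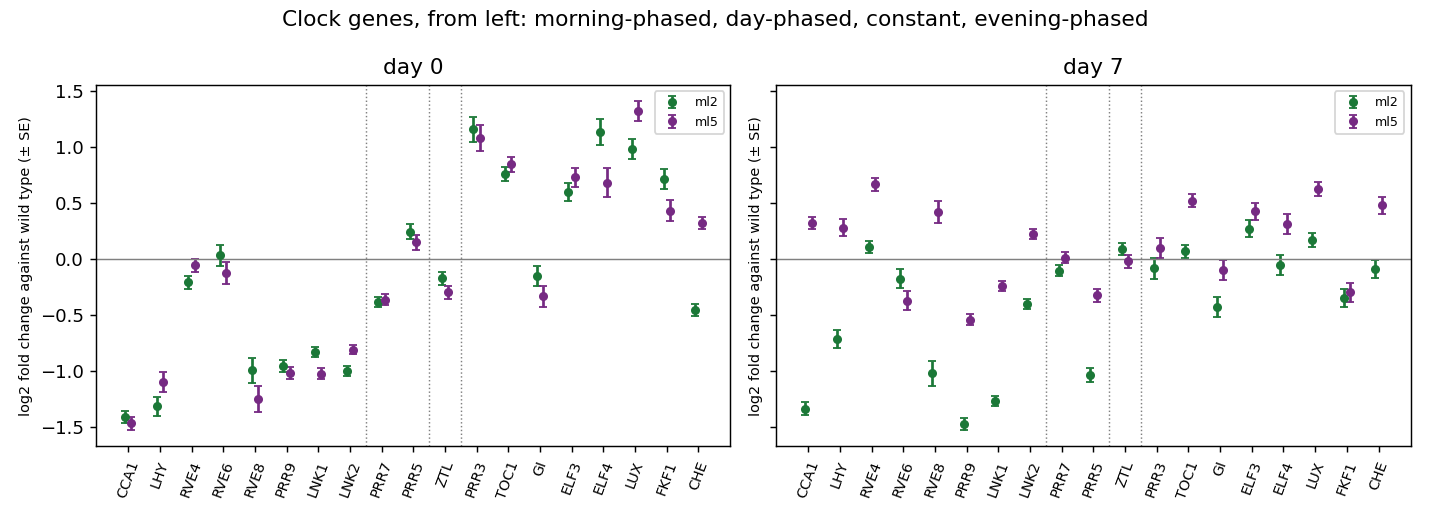
Log2 fold change ± SE of the 19 clock genes in ml2 and ml5 against WT at day 0 and day 7, ordered by textbook phase with dotted lines between phases. At day 0, 7 of 8 morning genes are lower in ml2 and 6 of 8 in ml5, and 6 and 7 of 8 evening genes are higher.

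Compared directly at day 0, ml5 had lower defence and senescence transcripts than ml2 and higher photosynthesis transcripts. PR1 stood at 5.53 ± 0.309 against 102 ± 7.45 CPM in ml2 (-4.20 ± 0.092, adjusted p = 3.37e-25). In the salicylic acid and immunity list, all 20 tested genes were lower (median -1.33, adjusted p = 2.6e-25). PR2 (-2.51 ± 0.055) and PR5 (-2.37 ± 0.083) were among them. Of the jasmonate genes, 17 of the 21 tested genes were lower and 4 did not pass, or 1 up and 18 down adjusted over the list alone (median -0.70, adjusted p = 2.14e-16). TAT3 (-3.10 ± 0.081) and PDF1.2 (-2.2 ± 0.071) were examples. Of the leaf senescence genes, 1 of the 24 tested genes was higher, 16 lower and 7 did not pass, or 1 up and 17 down adjusted over the list alone (median -0.48, adjusted p = 6.33e-09). SAG13 (-2.35 ± 0.10) and NAP (-1.27 ± 0.062) were among these. Of the endoplasmic reticulum chaperones, all 8 tested genes were lower (median -0.55, adjusted p = 5.07e-09), with BIP3 (-2.86 ± 0.24). In chlorophyll synthesis, 22 of the 23 tested genes were higher and 1 did not pass, or 23 up and 0 down adjusted over the list alone (median 0.54, adjusted p = 8.36e-25). PORB (0.84 ± 0.042) and CRD1 (0.70 ± 0.034) were among them. In the photosystem list, 34 of the 42 tested genes were higher and 8 did not pass, or 35 up and 0 down adjusted over the list alone (median 0.26, adjusted p = 4.04e-29). LHCB6 (0.55 ± 0.040) was among them. Among Calvin cycle genes, 19 of the 20 tested genes were higher and 1 lower (median 0.27, adjusted p = 9.75e-18). RBCS1A (0.59 ± 0.036) was among them. Of the chloroplast-encoded genes, 85 of the 88 tested genes were higher and 3 did not pass, or 87 up and 0 down adjusted over the list alone (median 1.28, adjusted p = 8.85e-51), at 0.743% ± 0.0643 of counts in ml5 against 0.309% ± 0.049 in ml2. Of the mitochondria-encoded genes, 27 of the 68 tested genes were higher and 41 did not pass (median 0.69, adjusted p = 4.15e-06, adjusted p = 0.136 with an estimated correlation). The largest rises besides ML2 included PHI-1 (5.77 ± 0.12), EXO (4.64 ± 0.12) and the touch-induced TCH4 (3.35 ± 0.069), and the largest falls besides ML5 included NIT2 (-4.58 ± 0.22) and MSRB8 (-4.29 ± 0.33). In all, 5589 of the 19493 tested genes passed, 2762 higher and 2827 lower, of which 277 and 540 differed by at least 2-fold. List calls numbered 16 of 30, 10 of them also with an estimated correlation. With library sizes alone as the scaling, the split was 1657 higher and 4524 lower (26.8% higher, against 49.4% with TMM). RLE size factors gave 2833 higher and 2744 lower (50.8%), and DESeq2 2638 and 2621 (50.2%). Without ml2 day 0 replicate 1, 6587 genes passed.

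At day 7, ml5 had lower senescence, starvation and amino acid catabolism transcripts than ml2. SAG12 stood at 3.71 ± 0.468 against 31.1 ± 0.615 CPM in ml2 (-3.06 ± 0.10, adjusted p = 2.96e-18). In leaf senescence, 1 of the 24 tested genes was higher, 20 lower and 3 did not pass, or 1 up and 21 down adjusted over the list alone (median -0.56, adjusted p = 8.78e-13). NAP (-1.11 ± 0.053) and ORE1 (-0.92 ± 0.052) were among them. Of the amino acid catabolism genes, 20 of the 25 tested genes were lower and 5 did not pass, or 0 up and 22 down adjusted over the list alone (median -0.37, adjusted p = 3.14e-11). PRODH2 (-1.11 ± 0.062) and GDH2 (-0.82 ± 0.042) were examples. Of the dark and sugar starvation genes, 10 of the 14 tested genes were lower and 4 did not pass (median -0.28, adjusted p = 2.73e-07), with DIN11 (-2.24 ± 0.077) and DIN2, at 704 ± 9.94 against 1422 ± 15.3 CPM. Of the autophagy machinery, 1 of the 44 tested genes was higher, 19 lower and 24 did not pass (median -0.15, adjusted p = 0.00617). ATG7 (-0.66 ± 0.070) and ATG14a (-0.60 ± 0.074) were among these. In the Calvin cycle, 18 of the 20 tested genes were higher and 2 did not pass (median 0.71, adjusted p = 8.14e-15). RBCS1A (1.37 ± 0.038) was among them. In the photosystem list, 37 of the 42 tested genes were higher, 2 lower and 3 did not pass (median 0.42, adjusted p = 4.43e-17, adjusted p = 0.0766 with an estimated correlation). LHCB5 (1.2 ± 0.041) was among them. Of the clock genes, 13 of the 19 tested genes were higher and 6 did not pass, or 15 up and 1 down adjusted over the list alone (median 0.45, adjusted p = 1.27e-09). CCA1 (1.66 ± 0.058) and LNK1 (1.02 ± 0.047) were among these. Of the ribosomal protein genes, 14 of the 16 tested genes were higher and 2 did not pass (median 0.53, adjusted p = 5.26e-11). RPS6B (0.95 ± 0.050) was among them. The largest rises besides ML2 included cPT4 (2.51 ± 0.10) and ACD6 (2.40 ± 0.072), and the largest falls besides ML5 included PGAZAT (-4.14 ± 0.10) and CYP71A13 (-3.40 ± 0.11). In all, 8064 of the 19493 tested genes passed, 3701 higher and 4363 lower, of which 347 and 693 differed by at least 2-fold. List calls numbered 16 of 30, 9 of them also with an estimated correlation. Scaled by library sizes alone, the split was 4954 higher and 3308 lower (60% higher, against 45.9% with TMM). The split was 3702 higher and 4340 lower (46.0%) with RLE size factors and 3484 and 4073 (46.1%) with DESeq2.

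The last question was whether darkness acted differently in the lines, tested as the difference between the response of a line and that of WT. Such a difference also arises where a line differs from WT at day 0 and nears it by day 7. It also carries the limits on harvest time at both days and on ageing. In ml2, OPR3 went by -1.62 in darkness against 0.88 in WT, a difference of -2.51 ± 0.074 (adjusted p = 9.86e-21). Of the jasmonate genes, 20 of the 21 tested genes responded lower and 1 did not pass (median -1.45, adjusted p = 1.11e-24). In the abscisic acid list, 12 of the 17 tested genes responded lower and 5 did not pass, or 0 up and 13 down adjusted over the list alone (median -0.85, adjusted p = 3.19e-08), with HAI1, also a senescence gene, at -3.24 ± 0.17. In leaf senescence, 1 of the 24 tested genes responded higher, 15 responded lower and 8 did not pass, or 1 up and 17 down adjusted over the list alone (median -0.79, adjusted p = 1.3e-09). Of the salicylic acid and immunity genes, 1 of the 20 tested genes responded higher, 13 responded lower and 6 did not pass, or 1 up and 14 down adjusted over the list alone (median -0.69, adjusted p = 7.6e-08). WRKY18 (-1.62 ± 0.090) was among them. Of the endoplasmic reticulum chaperones, 7 of the 8 tested genes responded lower and 1 did not pass (median -0.58, adjusted p = 9.31e-07). BZIP60 (-0.96 ± 0.084) was among them. Chlorophyll synthesis and Calvin cycle genes fell less than in WT, where 21 of the 23 tested genes responded higher and 2 did not pass, or 22 up and 0 down adjusted over the list alone (median 0.58, adjusted p = 1.14e-13) in the former and 18 of the 20 tested genes responded higher and 2 did not pass, or 19 up and 0 down adjusted over the list alone (median 0.50, adjusted p = 5.66e-15) in the latter, with HEMA1 (0.90 ± 0.061) and PRK (1.41 ± 0.077). Of the light signalling genes, 5 of the 12 tested genes responded higher, 2 responded lower and 5 did not pass, or 7 up and 2 down adjusted over the list alone (median 0.33, adjusted p = 0.0102). ATHB2 (1.39 ± 0.10) was among them. Against WT, medians at day 0 and day 7 were -0.55 and 0.025 for chlorophyll synthesis and -0.69 and -0.00955 for the Calvin cycle. They were 0.99 and 0.21 for leaf senescence, 1.41 and 0.39 for salicylic acid and immunity, and 0.45 and -0.045 for the chaperones. In these lists medians, not all members, neared WT. Those of jasmonate (1.23 and -0.30), abscisic acid (0.53 and -0.47) and light signalling (-0.089 and 0.13) changed sides. In all, 5660 of the 19493 tested genes passed, 2621 higher and 3039 lower, of which 417 and 869 differed by at least 2-fold. List calls numbered 15 of 30, 8 of them also with an estimated correlation. With library sizes alone as the scaling, the split was 1510 higher and 5102 lower (22.8% higher, against 46.3% with TMM), and that scaling moved the median of all genes by -0.15. RLE size factors gave 3102 higher and 2655 lower (53.9%), and DESeq2 2967 and 2558 (53.7%). Without ml2 day 0 replicate 1, 6836 genes passed, 5351 of them also called with it.

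In ml5, LHCB5 went by -5.55 in darkness against -7.30 in WT, a difference of 1.76 ± 0.057 (adjusted p = 7.65e-21), and DIN6 by 4.87 against 8.40, a difference of -3.53 ± 0.10 (adjusted p = 9.29e-22). In the photosystem list, 38 of the 42 tested genes responded higher and 4 did not pass (median 0.66, adjusted p = 1.42e-26). In the Calvin cycle, 19 of the 20 tested genes responded higher and 1 did not pass (median 1.02, adjusted p = 5.27e-23). FBA2 (1.72 ± 0.054) was among them. In chlorophyll synthesis, 14 of the 23 tested genes responded higher, 1 responded lower and 8 did not pass, or 14 up and 2 down adjusted over the list alone (median 0.30, adjusted p = 5.25e-06). CRD1 (0.90 ± 0.051) was among them. Of the jasmonate genes, 2 of the 21 tested genes responded higher, 18 responded lower and 1 did not pass (median -1.30, adjusted p = 4.16e-12). OPR3 (-1.84 ± 0.074) was among them. Of the abscisic acid genes, 2 of the 17 tested genes responded higher, 9 responded lower and 6 did not pass, or 2 up and 10 down adjusted over the list alone (median -0.67, adjusted p = 0.000983). HAI1 (-3.01 ± 0.17) was among them. In leaf senescence, 3 of the 24 tested genes responded higher, 14 responded lower and 7 did not pass, or 3 up and 15 down adjusted over the list alone (median -0.77, adjusted p = 8.1e-07). WRKY6 (-2.84 ± 0.11) was among them. Of the dark and sugar starvation genes, 2 of the 14 tested genes responded higher, 9 responded lower and 3 did not pass (median -0.56, adjusted p = 0.000292). Of the amino acid catabolism genes, 16 of the 25 tested genes responded lower and 9 did not pass (median -0.29, adjusted p = 5.02e-06). GDH2 (-1.02 ± 0.072) was among them. In the 26S proteasome, 17 of the 32 tested genes responded lower and 15 did not pass (median -0.23, adjusted p = 0.000476). RPT6B (-0.69 ± 0.086) was among them. Among the phloem markers, 1 of the 6 tested genes responded higher, 4 responded lower and 1 did not pass (median -0.51, adjusted p = 0.00692). SWEET12 (-2.31 ± 0.11) was among them. Against WT, medians at day 0 and day 7 were 0.81 and 0.087 for starvation and 0.25 and 0.0088 for amino acid catabolism. There medians, not all members, neared WT. Medians changed sides for photosystems (-0.10 and 0.46), the Calvin cycle (-0.41 and 0.71) and leaf senescence (0.19 and -0.44). So did jasmonate (0.42 and -0.46), abscisic acid (0.34 and -0.20), the proteasome (0.043 and -0.18) and phloem markers (0.24 and -0.31). Chlorophyll synthesis went from 0.0018 to 0.29. In all, 6906 of the 19493 tested genes passed, 3387 higher and 3519 lower, of which 780 and 919 differed by at least 2-fold. List calls numbered 14 of 30, 10 of them also with an estimated correlation. Scaled by library sizes alone, the split was 3626 higher and 3252 lower (52.7% higher, against 49.0% with TMM). The split was 3757 higher and 3139 lower (54.5%) with RLE size factors and 3576 and 3027 (54.2%) with DESeq2.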

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

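In this part, the tests on chloroplast transcripts, salicylic acid genes and the clock, and the choice of which interaction genes to list, were made after the result was seen; the counts over other splits of the libraries were planned.

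The dark response of ml2 differed from that of WT in 5660 genes. For several lists, the median difference from WT was smaller at day 7 than at day 0. List medians of the difference were -0.79 for leaf senescence, -1.45 for jasmonate, -0.85 for abscisic acid, -0.69 for salicylic acid and immunity and -0.58 for endoplasmic reticulum chaperones. They were 0.58 for chlorophyll synthesis, 0.50 for the Calvin cycle and 0.33 for light signalling. By gene, the log2 differences were HAI1 -3.24, OPR3 -2.51, WRKY18 -1.62, BZIP60 -0.96, HEMA1 0.90, PRK 1.41, ATHB2 1.39, PRP4 2.37, UGT76B1 -4.50, DIP2 -4.46 and LBD1 -4.33. Of 60 drawn splits of the libraries, only the real 1 gave as many genes; the highest other gave 5133. That split kept the real day 0 groups and exchanged 2 of the 3 day 7 libraries. The median of the other splits was 0. The splits exchange genotype within a day, so they stand for no genotype difference at all, not for an equal dark response. They therefore cannot tell an unequal dark response from a genotype difference on 1 day.

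The dark response of ml5 differed from that of WT in 6906 genes. For starvation and amino acid catabolism, the median difference from WT was smaller at day 7 than at day 0, while members still differed both ways. List medians were -0.77 for leaf senescence, -0.56 for starvation, -0.29 for amino acid catabolism, -1.30 for jasmonate, -0.67 for abscisic acid, -0.23 for the proteasome and -0.51 for phloem markers. They were 0.30 for chlorophyll synthesis, 0.66 for photosystems and 1.02 for the Calvin cycle. By gene, the log2 differences were WRKY6 -2.84, DIN6 -3.53, GDH2 -1.02, CRD1 0.90, LHCB5 1.76, FBA2 1.72, OPR3 -1.84, HAI1 -3.01, RPT6B -0.69, SWEET12 -2.31, LEA3 3.81, PHI-1 -6.01, ERF53 -5.85, ProT3 -5.57, EXO -5.31 and LBD1 -5.21. Of 60 drawn splits, only the real 1 gave as many genes; the highest other, which exchanged 2 day 0 libraries and kept the day 7 groups, gave 3191.

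For the 9 comparisons of 2 groups there are 10 splits each, and 1 of them, the real split, gave as many genes. The splits are too few for a share under 0.05. The real counts were 15964, 15548 and 15557 for darkness in WT, ml2 and ml5, 8677 and 5036 for ml2 against WT at day 0 and day 7, and 8064 for ml5 against ml2 at day 7, with 0 genes in the highest other split. The real count was 7467 for ml5 against WT at day 0, also with 0. It was 8444 for ml5 against WT at day 7 and 5589 for ml5 against ml2 at day 0, each with 1 gene in the highest other split.

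Chloroplast-encoded transcripts were lower in ml2 and higher in ml5 than in WT at day 0. Differences between libraries in carry-over of organelle RNA without a poly(A) tail may account for this: within groups, log2 chloroplast and mitochondria shares moved together over 18 libraries (Pearson r 0.909, Spearman 0.920, exact permutation p = 4.29e-05 within groups, two-sided, the same adjusted over 2 relations; r 0.896 without the 2 farthest libraries). For the fall in darkness, carry-over needs the mitochondria share to fall too. Its log2 ratio of day 7 to day 0 was 0.20 in WT and 0.55 in ml2, against -1.38 and -1.29 for the chloroplast share. With TMM, mitochondria list medians were -0.20 and 0.43. That argues against carry-over as the whole cause in ml2, unless mitochondria transcripts rose. In ml5 (ratios -0.28 and -2.45) and WT, part of the fall may be carry-over. Biological causes were not tested.

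Salicylic acid and immunity genes were higher in ml2 at day 0. If the WT libraries of day 0 stood apart, ml5 would show the same rise, and its median there was -0.024. Without ml2 day 0 replicate 1, the library that stands apart, the median was 1.39. These values argue against both as the cause; a difference in growth or health of the plants may remain and was not tested.

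Clock genes of morning and evening phase moved apart at day 0 in both lines: the median of evening members minus that of morning members was 1.71 in ml2 and 1.73 in ml5. A later harvest of the lines could give this and other day 0 differences. It cannot be told from a clock difference, as harvest times are unknown. A clock difference that kept its phase would show at day 7 if harvest times matched. The value there was 0.80 in ml2 (resampled interval 0.18 to 1.33) and 0.12 in ml5 (-0.32 to 0.76). Set against 0.5 of the day 0 value, these lay -0.056 (resampled interval -0.59 to 0.58) and -0.74 (-1.16 to 0.020) away. Day 7 harvest times are unknown too and intervals cover members only, so this decides neither line. The ml5 morning median went from -1.02 at day 0 to 0.25 at day 7. Phases were set after the values were seen, for all 19 members; a first set of 13 members gave 1.75, 1.79, 1.09 and 0.063 for ml2 and ml5 at day 0 and then at day 7. Resampled intervals were added later still.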

How the results depend on the processing

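Alternatives for the overlap of the lines were chosen after the result was seen; the others were planned. In the counts of called genes, all 225 alternatives lay within 1.5 times the reported value. The lowest and highest were 13740 (stricter filter) and 16668 (no filter beyond 1 count) for darkness in WT, 7429 (only the libraries compared) and 9357 (without ml2 day 0 replicate 1) for ml2 at day 0, 6512 and 7931 for ml5 at day 0, 4089 and 5665 for ml2 at day 7, and 7479 and 9759 for ml5 at day 7. For ml5 against ml2 they were 4068 and 6587 at day 0 and 7036 and 8553 at day 7, and for the differences in dark response 5015 and 6836 in ml2 and 6320 and 7929 in ml5.

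Leaving out 1 library gave 15533 to 15674 genes for darkness in WT, 15181 to 15566 in ml2 and 15076 to 15227 in ml5. It gave 7662 to 9357 for ml2 at day 0, 6512 to 6687 for ml5 at day 0, 4089 to 4515 for ml2 at day 7 and 7479 to 7591 for ml5 at day 7. Genes higher in both lines at day 0 ranged from 1996 (DESeq2) to 3057 (library sizes only), and lower in both from 2010 (library sizes only) to 2931 (RLE size factors). Which side of the split of called genes was larger changed with at least 1 of RLE size factors, library sizes alone and DESeq2 in every comparison but darkness in WT.

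The number of list calls moved most. Of 330 list tests 167 were called, 98 with an estimated correlation and 264 with fry, 151 to 169 with 1 library left out and 168 with replicate number as a block; the cause was not tested. Among named genes, 14561 values were the same, 181 weaker, 6 stronger and 1 reversed. The reversed value was FAMA in the dark response of ml5, with a log2 fold change of 0.12 with library sizes alone; the cause was not tested.

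Replicate numbers were checked for pairing of libraries across groups. In 45 correlations between groups the values ran from -0.12 to 0.077, median -0.0046, and 3 of 18 libraries were closest to those of their own number. With replicate number as a block, 15887 genes were called for darkness in WT, 8516 for ml2 at day 0 and 8444 became 8272 for ml5 at day 7.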

Other observations

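The observations here were chosen after the result was seen. Several of the genes with the largest changes at day 0 were shared by the lines. MRD1 was lower in ml2 (-5.02 ± 0.28) and ml5 (-4.76 ± 0.29), and EXPA16 (4.04 ± 0.21 and 4.67 ± 0.20), MLO12 (3.87 ± 0.16 and 4.31 ± 0.15) and ERF53 (3.67 ± 0.16 and 4.64 ± 0.16) were higher. Both lines are compared with the same 3 WT libraries, so a state of those WT leaves would give such a shared change as well. Of these 4, only MRD1 kept its direction past the threshold at day 7, against other WT libraries, with log2 fold changes of -2.88 ± 0.22 in ml2 and -3.26 ± 0.22 in ml5. The day 7 values of the other genes, outside the naming rule, were -0.10 ± 0.17 in ml2 (did not pass) and -1.21 ± 0.20 in ml5 (lower) for ERF53, -0.39 ± 0.087 (lower) and -0.10 ± 0.084 (did not pass) for MLO12, and 0.46 ± 0.48 and 0.90 ± 0.44 for EXPA16, neither of which passed.

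Before darkness, PR1 was higher in ml2 (2.71 ± 0.078) and lower in ml5 (-1.49 ± 0.11), while the salicylic acid and immunity list as a whole did not pass in ml5. In darkness, ml5 retained more LHCB5 (1.62 ± 0.042 against WT) and had less SAG12 (-4.57 ± 0.091), while DIN6 was already higher in ml5 before darkness (3.44 ± 0.085). A slower course of senescence in ml5 is 1 hypothesis and was not tested, since only 1 dark time point was sampled. Samples from several days of darkness would decide it: under a slower course, LHCB5 and SAG12 in ml5 would reach the WT levels of day 7 at a later day.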
